A study of Papio anubis with 24 samples.

How the data were processed

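DNA methylation was profiled in olive baboon (Papio anubis) pluripotent cells by MeDIP-seq, in which fragmented DNA is immunoprecipitated with an antibody against methylated cytosine and sequenced beside an input library of the same kind of DNA without the precipitation. The labels give 24 libraries in 4 groups of 6: MeDIP and input libraries of embryonic stem cells (ESC, from the lines titled ESC_B4 and ESC_B15) and of induced pluripotent stem cells (iPSC, from the lines titled iPSC_160-2 and iPSC_M14939#3), with 3 replicates per line in each group. Per the labels' protocols, the cells were grown on feeder cells. Libraries were grouped by their titles. For 5 of the 6 libraries of line M14939#3 the cell line label carries another number after the hash sign than the title does, and both place the library in the iPSC groups.

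The deposited data analysed here are 2 peak lists, 1 for ESC and 1 for iPSC. SAMtools 1.10, Picard 2.239, MACS2 and deepTools are named in the submitters' processing notes. The version and options of MACS2, the aligner, the genome build, and how the 6 MeDIP and 6 input libraries of a cell type were combined are not given in the sources used here. Each list holds the start, end and summit of every peak and 4 values per peak, all of them the authors' own. The deposited fold enrichment is a linear ratio of the pileup of fragments at the summit to a local background. The deposited −log10 p-value and −log10 q-value belong to the same comparison within that list. The deposited score is 10 times the −log10 q-value without its decimals, which held for 99.99% of ESC and 99.98% of iPSC peaks. The smallest −log10 q-value was 1.30 in both lists, a q of 0.05. With 1 list per cell type there is no value per library or per line, so there is no replicate error, no p-value for a difference between the cell types, and cell type cannot be separated from line.

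Peaks were compared by overlap with bedtools 2.31.1, counting an overlap of at least 1 bp. The overlap was set against 100 circular shifts of the iPSC peaks within each chromosome, by at least 1 Mb, which keep widths and spacing but not the place of dense regions. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and treat peaks as independent, which neighbouring peaks are not. The span of a chromosome was taken as the end of its last peak in either list, so distances to the distal end are measured from that peak. Peaks on unplaced scaffolds and on the mitochondrial sequence were left out of values per chromosome. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

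Read depth is not given in the lists, but the pileup and the background behind each peak could be recovered from the deposited fold and −log10 p-value, taking the fold as a ratio with 1 added to both terms and the p-value as a Poisson tail. The recovered pileup was a whole number of fragments, or a whole number times 1 common factor, within 0.02 for 100% of the peaks of both lists. The step was tested on simulated peaks, of which at least 99.98% were recovered. These were made with the same formulas, so they check the inversion, not whether the deposited values follow the formulas. The common factor of the iPSC list was fitted to that list. In the ESC list the pileup was unscaled and the background moved in steps of 0.895, while in the iPSC list the pileup carried a factor of 0.690 and the background none. Such factors arise when the deeper of the treatment and control libraries is scaled down, so the background was read as coming from the input libraries. It moved in these steps for 89.4% of the ESC peaks of intermediate background, leaving out those near the lowest and the highest values. The ESC step was chosen to make this share largest. For iPSC the share was 81.9% of all peaks, so the shares are not directly comparable. The lowest background, taken as the mean over the genome, was 12.0 fragments for ESC and 10.2 for iPSC, a ratio of 1.17. Without scaling, MeDIP coverage was 1.24 times higher for iPSC than for ESC, and input coverage was 1.31 times higher for ESC than for iPSC. The narrowest peaks were 177 bp (ESC) and 190 bp (iPSC) wide.

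The only annotation at hand is of the assembly Panubis1.0. On 11 of 21 chromosomes the peaks run past its last gene, on 10 of them by more than 1 Mb, so the lists use another build. Positions are therefore given as the lists give them, counted from 1, with chromosome numbers as in the lists, and no gene, promoter or CpG island was assigned. The planned results on promoters, CpG islands and gene lists were not run. By the rule written before the data were examined, without an annotation of the build the 10 peaks of highest fold in each class (overlapping, ESC list alone, iPSC list alone) are named by position. For overlapping peaks the iPSC fold sets the order. Alternatives chosen before the data were examined were a −log10 q of at least 5, an ESC list of the length of the iPSC list, merging of peaks within 500 bp, overlap of 50% of both peaks, and random placement. Added after seeing the data were a rescoring of the ESC peaks at the iPSC background, all values by distance to a chromosome end, counts in 1 Mb windows, and a search for stretches of at least 20 kb in which neighbouring peaks lie at most 2 kb apart.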

Results

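The data comprised 1 MeDIP-seq peak list for baboon ESC and 1 for baboon iPSC, and the labels give each cell type 2 lines with 3 MeDIP and 3 input replicates per line. How these libraries were combined into a list is not given in the sources used here. In each list a peak marks a stretch where DNA carrying methylated cytosine was enriched over the local background. The series set reprogrammed cells beside embryo-derived cells for DNA methylation, and the comparison asks how far the enriched sites of the 2 cell types coincide. As each cell type has a single list, every difference below is a difference between 2 lists, with no replicate error and no test between cell types.

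The ESC list held far more enriched sites than the iPSC list. It had 166961 peaks covering 41.4 Mb, against 44434 peaks covering 14.2 Mb for iPSC, which is 3.76 times as many peaks and 2.92 times the length. Peaks of the iPSC list were fewer but wider, with a median width of 242 bp (interquartile range 208 to 331 bp) against 215 bp (191 to 270 bp) for ESC. The narrowest peaks differed too, at 190 bp for iPSC and 177 bp for ESC, so part of the difference in medians may lie in this lower limit. Peaks of 1 kb or more made up 2.10% of the iPSC list (931 peaks) and 0.117% of the ESC list (196 peaks). The widest iPSC peak spanned 5977 bp on chromosome 1 (51484739 to 51490715) and the widest ESC peak 3380 bp on chromosome 4 (162833490 to 162836869), and both overlapped a peak of the other list. The median deposited fold enrichment was 2.58 for iPSC and 2.27 for ESC, each relative to its own input-based background, so the levels of the lists are not directly comparable.

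As deposited, most iPSC peaks lay on ESC peaks, whereas most ESC peaks had no iPSC counterpart. Of the iPSC peaks, 29447 (66.3%, 95% interval 65.8 to 66.7%) overlapped an ESC peak. Of the ESC peaks, 29879 (17.9%, 17.7 to 18.1%) overlapped an iPSC peak. Among placed peaks the shares were 66.4% for iPSC and 17.8% for ESC. Shifted iPSC peaks gave 3.70% and 0.987% on average, with maxima of 4.19% and 1.12% over 100 shifts, so the shares among placed peaks were 17.9 and 18.0 times the shifted means. The shifts move peaks out of dense regions that both lists share, so these multiples include shared regional density as well as coinciding sites. In bases, the lists shared 7.56 of the 48.0 Mb covered by either, or 15.7%. With the ESC list reduced to its 44434 peaks of highest −log10 q, 28.6% of iPSC peaks overlapped an ESC peak and 28.5% of ESC peaks an iPSC peak, shares that lists of equal length make nearly equal by construction, since most overlapping peaks pair singly.

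Overlap was more frequent among ESC peaks of high rank. With each list divided into 10 equal bins by −log10 q, the overlapping share of ESC peaks went from 12.8% (12.3 to 13.4%) in the lowest bin to 37.6% (36.9 to 38.4%) in the highest. In the iPSC list it went from 56.0% (54.6 to 57.5%) in the lowest bin to 73.6% (72.3 to 74.9%) in the ninth and 71.0% (69.7 to 72.3%) in the highest. The recovered background separated the ESC peaks further. Of 4 equal bins of ESC peaks by background, the lowest had 1.44% overlapping an iPSC peak and the highest 45.7%. For iPSC these shares were 54.0% and 81.0%. Overlapping ESC peaks had a median width of 258 bp and a median fold of 2.06, and the other ESC peaks 209 bp and 2.32.

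**Figure D1:**
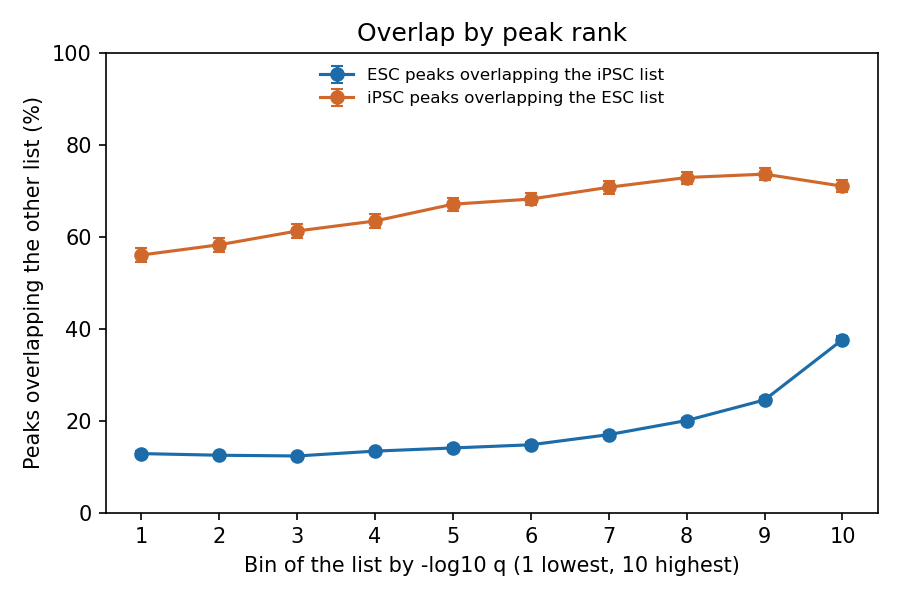
Percentage of peaks overlapping the other list (vertical axis) in 10 equal bins of each list ordered by the deposited −log10 q (horizontal axis, 10 highest), with exact 95% counting intervals as bars. The ESC share lies between 12.3% and 14.8% in the first 6 bins and reaches 37.6% in the highest, and the iPSC share lies between 56.0% and 73.6%.

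Pairs of peaks that overlapped each other and no further peak allowed the same 28664 sites to be set side by side. The deposited fold was higher in the iPSC list at 76.8% of them (76.3 to 77.3%), with medians of 2.58 for iPSC and 2.08 for ESC. The recovered pileup relative to the mean genome background ran the other way: it was 9.68 times that background in ESC and 7.02 times in iPSC at the median, and it was higher in iPSC at 3.26% of the sites (3.06 to 3.47%). The local background differed more than the pileup did, at 4.48 times the genome background in ESC and 2.64 times in iPSC, and was relatively higher in ESC at 96.4% of the sites. The pairs hold only sites called in both lists. At a lower background a higher fold is needed to pass, and the smallest −log10 p was 3.23 for iPSC against 2.76 for ESC. Selection may therefore raise the iPSC folds at these sites, which was not tested.

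Named by position, the 3 overlapping peaks with the highest iPSC fold lay on chromosome X at 113208172 to 113208471 (iPSC fold 8.33, ESC fold 2.57), on chromosome 14 at 1314032 to 1314359 (7.99 and 1.62) and on chromosome 12 at 15268647 to 15269035 (7.68 and 1.52). All 10 of this class had iPSC folds of 6.93 to 8.33 and ESC folds of 1.27 to 2.57, and 4 of them lay on unplaced scaffolds. Among peaks in the ESC list alone, the highest folds were on chromosome 5 at 22100962 to 22101237 (7.14), chromosome X at 122190785 to 122191453 (6.72) and chromosome 3 at 130145206 to 130145443 (6.70). The 10 of this class had folds of 5.85 to 7.14 and lay 22422 to 405054 bp from the nearest iPSC peak. Among placed peaks in the iPSC list alone, the highest folds were on chromosome 4 at 161592891 to 161593234 (7.24), chromosome 8 at 140222831 to 140223161 (7.09) and chromosome 16 at 66151305 to 66151914 (6.79). Of the 10 in this class, with folds of 6.60 to 7.44, 4 were on unplaced scaffolds, and those with an ESC peak on the same sequence lay 321 to 12569 bp from it. The recovered background was low at all of these peaks. It was at most 15.2 fragments for the 10 in the ESC list alone, against a median of 29.5 over that list. In iPSC it was at most 18 for the 10 in that list alone and 14 for the overlapping 10, against a median of 25.3. The fold is a ratio to the background, so this order favours sites of low background. Genes at these positions are not given, because the build of the lists is not given in the sources used here.

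In both lists chromosome 19 had the densest peaks and chromosome 2 the sparsest among autosomes. Chromosome 19 carried 142.9 ESC and 51.7 iPSC peaks per Mb, and chromosome 2 carried 40.6 and 7.96, against 58.5 and 15.7 over all autosomes. The iPSC list held 36.2 peaks for every 100 ESC peaks on chromosome 19 and 19.6 on chromosome 2, the highest and lowest autosomes. Over 2748 windows of 1 Mb the peak counts of the lists ranked alike, with a Spearman correlation of 0.874 across windows, which are not independent replicates. All windows had at least 1 ESC peak, and 101 had no iPSC peak.

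**Figure D2:**
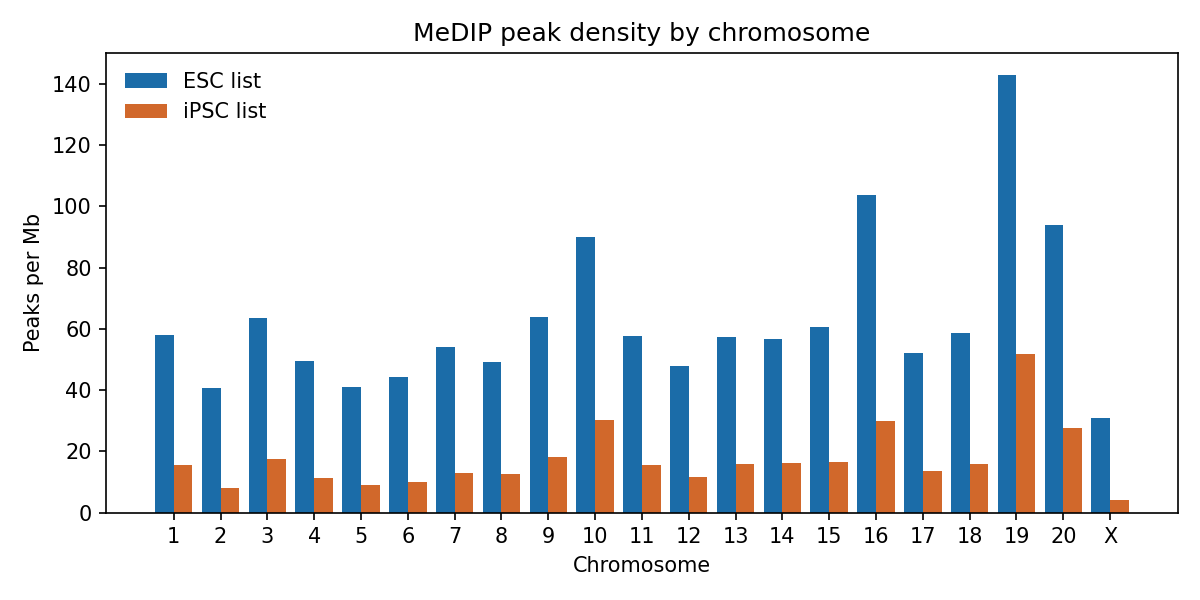
MeDIP peaks per Mb (vertical axis) on each chromosome (horizontal axis, numbered as in the peak lists), with a bar for each list. Chromosome 19 has the highest density in both lists, at 142.9 (ESC) and 51.7 (iPSC) peaks per Mb, and chromosome X the lowest, at 30.7 and 4.18.

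The X chromosome carried fewer peaks for its length than the autosomes, and the gap was wider in the iPSC list. ESC had 4412 peaks on X (30.7 per Mb), which is 0.525 of the autosomal density (0.510 to 0.541). In iPSC the X held 601 peaks (4.18 per Mb), or 0.267 of the autosomal density (0.246 to 0.290). The ratio between these values was 0.509 (0.467 to 0.555), and it lay between 0.491 and 0.509 over the deposited lists and 4 alternatives. There were 13.6 iPSC peaks for every 100 ESC peaks on X, below every autosome. The recovered input-based background at overlapping peaks was 1.03 times the autosomal median on X in ESC (resampling SD 0.025, 376 peaks) and 0.593 times in iPSC (SD 0.021, 372 peaks). Over all peaks of each list, which are different sites, it was 0.906 times in ESC and 0.638 times in iPSC. The overlapping share on X was 61.9% for iPSC peaks, against 66.5% on autosomes, and 8.52% for ESC peaks, against 18.1%.

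Peaks were concentrated toward chromosome ends, more so in the iPSC list. Within 5 Mb of an end lay 32.0% of iPSC peaks (31.6 to 32.5%) and 21.5% of ESC peaks (21.3 to 21.7%), where an even spread would give 7.67%. The iPSC share was higher on 20 of 21 chromosomes, with differences from −0.197 to 16.7 percentage points. Among overlapping peaks, 33.5% in iPSC and 33.7% in ESC lay near the ends. These are largely the same sites in both lists, so the shares are nearly equal by construction. Peaks without overlap had 29.1% in iPSC and 18.8% in ESC. Of the 10 densest 1 Mb windows, 9 in each list lay within 5 Mb of an end. The densest ESC window was the first Mb of chromosome 19, with 384 ESC and 150 iPSC peaks, and the densest iPSC window was the first Mb of chromosome 6, with 163 iPSC and 303 ESC peaks. The input-based background at overlapping peaks was also higher near the ends, by 1.25 times in ESC and 1.24 times in iPSC.

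**Figure D3:**
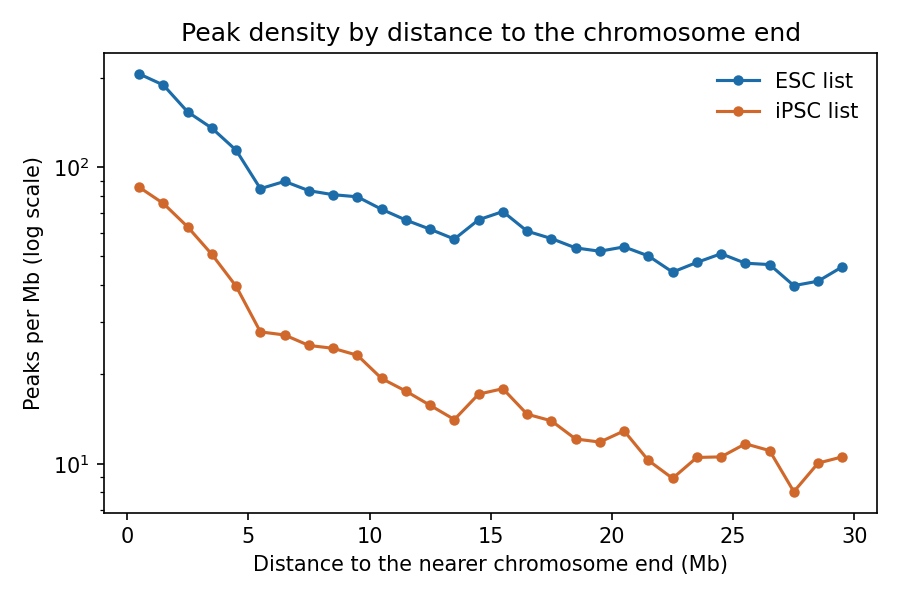
Peaks per Mb (vertical axis, log scale) against the distance to the nearer chromosome end in Mb (horizontal axis), 1 point per Mb and list over the chromosomes long enough to reach that distance. Density goes from 206.1 (ESC) and 85.5 (iPSC) peaks per Mb in the first Mb to 46.1 and 10.6 in the last Mb drawn.

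In 1 of the 2748 windows the iPSC list held more peaks than the ESC list: from 28 to 29 Mb on chromosome X, with 49 iPSC and 30 ESC peaks. There 47 iPSC peaks stood side by side from 28159044 to 28219406, a stretch of 60.4 kb of which they covered 77.7%. Their median width was 930 bp, and 20 of them were 1 kb or wider. Folds ran from 1.65 to 4.16 with a median of 2.55. No ESC peak lay inside the stretch, where the mean ESC density on X of 30.7 peaks per Mb would put only a few. It was the only stretch of at least 20 kb in the iPSC list in which peaks followed each other within 2 kb. The ESC list had 6 such stretches, the most fully covered at 56.8%, on chromosome 6 from 56877 to 77987, where 13 of its 18 peaks overlapped iPSC peaks. The stretch on X was singled out after its values were seen.

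**Figure D4:**
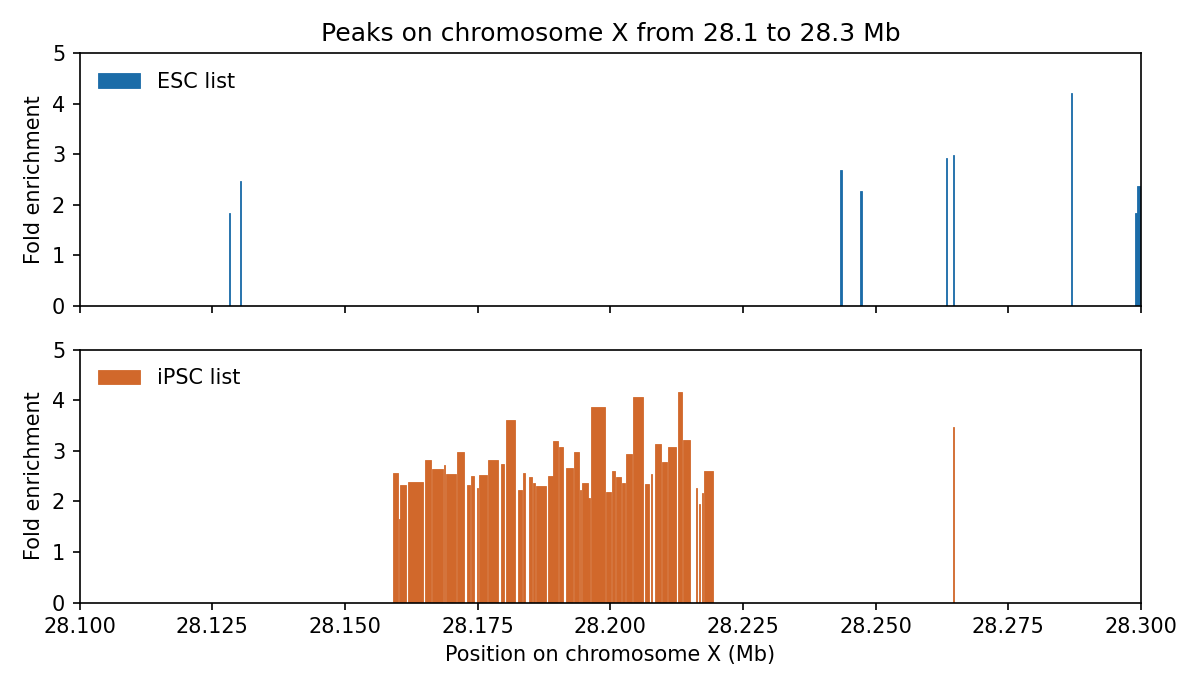
Deposited fold enrichment (vertical axis) of each ESC peak (upper panel) and iPSC peak (lower panel) around the stretch on chromosome X (horizontal axis, position in Mb), each bar as wide as its peak. The 47 iPSC peaks between 28159044 and 28219406 fill 77.7% of the stretch, where the ESC list has no peak.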

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

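Chosen before the result was seen were the test of sequencing depth for the length of the ESC list and the test of whether coverage alone explains the iPSC density on X. The tests of immunoprecipitation, of X copies, and both tests on the stretch of iPSC peaks on X were chosen after their results were seen. The sources name no group other than cell type, with line confounded with it.

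Signal also lay on sequences that the values per chromosome leave out. The ESC list had 4 peaks on the mitochondrial sequence, with folds of 1.19 to 1.49 over backgrounds of 234.1 to 295.3 fragments, and the iPSC list had 0. Unplaced scaffolds held 6.54% of ESC peaks and 7.30% of iPSC peaks.

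The ESC list was 3.76 times as long as the iPSC list. The lower background behind the iPSC list did not account for this in a rescoring. With ESC pileup and background scaled to the iPSC background and the iPSC threshold applied, 160220 ESC peaks were left, still 3.61 times the iPSC number. Only ESC peaks already called were rescored, by a fixed factor and without sampling loss. A larger part for sequencing depth can therefore not be excluded. Weaker immunoprecipitation in the iPSC libraries stays open, because the measures at the same sites oppose each other: the fold was higher in iPSC at 76.8% of paired sites, while the pileup relative to the genome background was higher in iPSC at only 3.26%. Paired sites are those called in both lists, and this selection may itself raise the iPSC fold. Less DNA methylation in the iPSC lines at the sites called in ESC alone is a hypothesis that was not tested, and the input-based background at paired sites differed between the lists, at 4.48 times the genome background in ESC and 2.64 times in iPSC.

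The X chromosome held relatively fewer iPSC peaks. Fewer X copies per cell in the iPSC lines is a candidate explanation: the X to autosome ratio of the input-based background was lower in iPSC by 0.440 at overlapping peaks (1.03 against 0.593), and less so over all peaks (0.906 against 0.638). The sex and karyotype of the lines are not given in the sources used here. No value per line exists to tell a loss of X from a male line, or whether 1 or both iPSC lines are concerned. Rescored at the X coverage, 0.901 of the autosomal iPSC peaks would still pass, against a density ratio of 0.509 (0.467 to 0.555). In this rescoring lower X coverage did not set the whole drop. The rescoring uses peaks already called and allows for no sampling loss, so it cannot exclude a larger part for coverage. Less methylation on the iPSC X chromosomes stays open and untested.

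The stretch of 47 iPSC peaks on X spanned 60.4 kb without any ESC peak. A gain of DNA copies in at least some of the iPSC libraries is a candidate explanation. The median input-based background in the stretch was 1.67 times that of the other 554 iPSC peaks on X (25.1 against 15). The median over all iPSC peaks was 25.3, so the stretch was raised against the rest of X but not against the whole list. It also lay above each of the 508 runs of 47 neighbouring X peaks, which reached at most 18.0. With 4.18 iPSC peaks per Mb on X, such runs span far more than 60.4 kb. They therefore cannot show whether rises this local occur elsewhere on X. Whether a gain alone, which raises MeDIP and input together, would give peaks of these folds was not tested. A repeat collapsed in the reference cannot be told apart from it, because the ESC list has 0 peaks in the stretch and so shows no ESC coverage there. Dense methylation of the stretch in the iPSC lines remains possible and was not tested separately.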

How the results depend on the processing

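Chosen after seeing the data were the rescoring of ESC peaks at the iPSC background and all values by distance to chromosome ends; the other alternatives were planned. The number of peaks stayed within 1.5 times the main count in every alternative run for it, with 3.47 to 3.76 ESC peaks per iPSC peak. The X to autosome ratio was 0.517 to 0.537 for ESC and 0.254 to 0.267 for iPSC, within the counting intervals. Random placement gave 3.73% and 0.992% overlap. The share of iPSC peaks on ESC peaks was 58.0% at a −log10 q of at least 5, 28.6% with ESC at the iPSC length, 67.2% after merging, 59.1% for overlap of 50% of both peaks and 64.6% after rescoring. The share of ESC peaks on iPSC peaks was 16.8%, 28.5%, 18.1%, 15.7% and 18.1% in the same order. A shorter ESC list holds fewer sites to meet. For other moves the cause was not tested. Near chromosome ends lay 22.3% of ESC and 33.3% of iPSC peaks at a −log10 q of at least 5, 20.1% and 31.2% after merging, 10.6% and 16.4% within 2 Mb, 32.7% and 45.1% within 10 Mb, and 25.0% of ESC peaks at the iPSC length, with iPSC above ESC in each. No paired analysis was possible because each cell type has 1 list and no column per replicate, which also ruled out leaving out replicates. Promoters, CpG islands and gene lists were not run for want of an annotation of the build. Depth per library is unknown.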

Other observations

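No test in this part was planned, and the values were looked up after the lists were seen. Of the 931 iPSC peaks of 1 kb or more, 64.3% (exact 95% interval 61.2 to 67.4%) overlapped an ESC peak, and of the 877 placed ones 43.2% (39.9 to 46.6%) lay within 5 Mb of a chromosome end. Of the 196 ESC peaks of this width, 85.2% (79.4 to 89.9%) overlapped an iPSC peak and 48.9% (41.4 to 56.4%) of the 180 placed ones lay near an end, so the shares near an end overlap in their intervals. The X stretch of dense iPSC peaks held 20 of the wide iPSC peaks.

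The window with the lowest iPSC share among those with at least 50 peaks lay on chromosome X from 91 to 92 Mb, with 54 ESC peaks and 1 iPSC peak, an iPSC share of 1.82% (0.046 to 9.72%) against 20.9% over all windows. Of the 10 such windows with the lowest share, 2 lay on X, and 3 did when windows were ordered by the upper limit of the interval. Without the stretch of 47 peaks, the iPSC density on X would be 0.246 of the autosomal density.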
